A study of Rattus norvegicus with 4 samples.

How the data were processed

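Single-cell RNA sequencing libraries came from rats aged 12 months, from the tibialis anterior (TA), a limb muscle, and from the extraocular muscles (EOM), which move the eye. The series holds 4 libraries, 1 for each combination of muscle and disease state, wild-type (WT) or DMD, the abbreviation the labels use. Per the labels' protocols, muscle was digested with enzymes and total cells were run on the Chromium droplet system of 10x Genomics with 3' chemistry version 3.1. Reads were counted with Cell Ranger 4.0.0, per the file headers, and the genome build was rn6, per the submitters' processing notes. The annotation, the read filters and the cell calling settings are not given in the sources used here. The deposited values are whole-number counts of unique molecular identifiers (UMIs) per gene and barcode, not normalized by the authors, over 25399 genes with the same feature table in each library. A 3' tag reports the end of a transcript and carries no information on exons far from it.

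Groups were taken from the disease state field of the labels. In all 4 samples the sample title states the opposite disease state from that field, and no other label settles which is right. The text therefore speaks of the library labelled WT or labelled DMD, meaning the disease state field. Reading the titles instead would turn every DMD over WT direction in both muscles by construction. The tissue contrasts would keep their direction, with the pair called WT and the pair called DMD exchanged.

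The deposited matrices held 3550 barcodes for TA labelled WT, 8944 for TA labelled DMD, 1917 for EOM labelled WT and 3093 for EOM labelled DMD, 17504 in all. Their total UMI counts were 9955900, 20685086, 9468266 and 14953593 in the same order. The lowest barcode held 500, 500, 501 and 500 UMIs, so the planned minimum of 500 UMIs removed none. Barcodes with under 200 genes or with over 20% mitochondrial UMIs were left out. The kept cells numbered 2119, 8549, 1262 and 2303, 14233 in all. Among kept cells, 13.4%, 42.8%, 5.31% and 7.64% had under 1000 UMIs.

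Doublets were scored per library with scrublet, as implemented in scanpy. Its automatic threshold marked 29 of the 14233 cells (0.204%), which is too few for a working call. In its place, and after that result was seen, the highest scores were removed up to an expected rate of 0.8% per 1000 cells. This took out 36, 585, 13 and 42 cells, 676 in all, and left 2083, 7964, 1249 and 2261 cells, 13557 in all. In TA labelled DMD the removed cells had a lower median UMI count (897) than the others (1221.5), while in the other libraries they had a higher one (3204 against 2482, 7846 against 3654 and 8100 against 4486). Median UMIs per analysed cell were 2482, 1221.5, 3654 and 4486, so TA labelled DMD was the shallowest library per cell.

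The 4 libraries were clustered together without batch integration, on log counts scaled to 10000 per cell, 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1.0, which gave 33 clusters. Classes were named from markers of 23 cell types fixed before the data were examined. The rule for scoring those markers was settled after the clusters had been seen, and 3 scorings were looked at. A class qualified with at least 3 markers at 2-fold or more over the median cluster and detected in 10% of the cluster's cells, and the class with the highest mean fold named the cluster. If another class had more markers among the 10 leading genes, that class was used where it qualified and the cluster stayed unnamed otherwise. Shallow clusters with no marker of their own among the leading genes also stayed unnamed. This left 3 clusters unnamed. The names are therefore rebuilt from the counts, as "X-like", and not the authors' own.

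Counts were summed per library and class and divided by the class total to give CPM, counts per 1000000. Log2 ratios used a prior of 10 CPM on both sides. A class entered a contrast with at least 50 cells in both libraries. The comparisons were TA labelled DMD against TA labelled WT, EOM labelled DMD against EOM labelled WT, EOM against TA labelled WT, and EOM against TA labelled DMD. The tissue contrasts share their libraries with the disease contrasts, so the 4 contrasts are not independent. Each contrast sets 1 library against 1, which leaves no replicate to test it with. A model with muscle and label as additive terms over the 4 libraries was not fitted, no test across libraries was run, no p-value was computed, and no difference has a replicate check. Shares carry exact Clopper-Pearson intervals and CPM values exact Poisson intervals at the 95% level. Fold intervals are likewise counting intervals. All of them cover counting error only, not the difference between animals or digestions. The intervals of CPM values, folds and list medians treat each UMI as independent, so they also leave out the variation between cells. Where a count was 0, the limit of 3 counts is used, and folds against 0 set the observed CPM against that limit. They are printed as "at least" but leave out the counting error of the other library, so they are not 95% lower ends.

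A total of 27 gene lists was fixed before the data were examined. For each, the median log2 ratio of members with at least 20 CPM in 1 of the compared libraries was set against 10000 random lists of the same size matched on mean expression. The percentile describes these libraries and is not a test. Counting intervals of list medians came from 500 Poisson redraws of the counts. A list is described as apart when its percentile was at or beyond 2.5 or 97.5 and its counting interval excluded 0. A list needed 3 measured members. In total 28 fixed genes or older symbols had no entry under that name in the feature table and were not analysed here, among them Pecam1, Col1a2, Cd36, Ackr1, Ttn and Xist.

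Named genes followed a rule fixed beforehand. In FAP/fibroblast-like, satellite-like, macrophage/monocyte-like and endothelial-like cells, the 3 highest and 3 lowest log2 ratios per contrast were taken. Such a gene needed at least 30 UMIs and 100 CPM in the higher library. Mitochondrial, ribosomal protein, haemoglobin and immunoglobulin genes, markers of another class and genes without a proper symbol were left out. The gene also had to reach at least 25% of its highest level in any class of that library, as a guard against free RNA, that is, transcripts from other cells in the droplet. Members of the fixed lists with at least 20 CPM in 1 library could be named too. Some genes that this rule names are not reported here. Shares of cells with a UMI were taken after thinning each cell to 1000 UMIs, with shallower cells left out.

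Alternatives planned beforehand were doublet calls kept, Leiden resolutions of 0.5 and 2.0, each library clustered alone, at least 1000 UMIs with at most 10% mitochondrial UMIs, a denominator without immune-like cells, TMM scaling (edgeR 4.0.16 in R 4.3.3), the mean over cells of each cell's CPM, thinned cells, a prior of 1 CPM, and lists of all members with a UMI. Chosen after seeing the data were lists limited to members that pass the free RNA guard, and satellite-like cells without the Myog-led cluster. Of the results recomputed, 8 share ratios and 18 list medians are treated in full. That selection was also made after the values were seen.

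The ratio and list steps were tested on simulated counts drawn from the real means and totals, with 200 genes of at least 100 CPM altered. Genes were drawn independently of each other and without free RNA. The simulation thus does not cover altered genes under that level or lists whose members move together. All altered genes came back in the right direction. For satellite-like cells in TA (1560 genes), 94.8%, 95.5%, 94.0% and 93.8% of genes altered by a log2 of -2, -1, 1 and 2 were recovered within 0.5. The shares for satellite-like cells in EOM (1362 genes) were 90.8%, 100%, 100% and 98.1%. For endothelial-like cells they were 100% at each size in TA (1634 genes) and 98.0%, 100%, 100% and 98.2% in EOM (1704 genes). A planted list reached percentile 100 in each of these 4 comparisons. Of unchanged lists, 3%, 6%, 5% and 8% fell outside the central 95% range, in the same order. Computations used Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and igraph 0.11.9.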

Results

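Total cells of the tibialis anterior and the extraocular muscles were profiled by 3' single-cell RNA sequencing in rats aged 12 months, with 1 library labelled WT and 1 labelled DMD per muscle. Duchenne muscular dystrophy is caused by loss of dystrophin, and the extraocular muscles are known to be relatively spared by it. The series thus sets a limb muscle beside a spared one, in each disease state. After filtering, 2083 cells remained for TA labelled WT, 7964 for TA labelled DMD, 1249 for EOM labelled WT and 2261 for EOM labelled DMD, with 6725438, 19196936, 6522986 and 12113554 UMIs. Intervals in parentheses are 95% intervals that cover counting error only, and no difference below has a replicate check. Genes called ranked were picked by log2 ratio with a prior of 10 CPM among genes with at least 100 CPM that met the other limits of the naming rule, so other genes below can have larger folds.

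The disease state field and the sample titles contradict each other in all 4 samples, so every DMD over WT direction rests on that field. The gene that encodes dystrophin, Dmd, was looked at first. Over all analysed cells it stood at 29.6 CPM (25.6 to 34.0) in TA labelled WT, 25.4 (23.2 to 27.7) in TA labelled DMD, 26.8 (23.0 to 31.1) in EOM labelled WT and 21 (18.5 to 23.7) in EOM labelled DMD. In satellite-like cells the values were 126 CPM (91.0 to 171), 65.7 (49.8 to 85.1), 66.9 (49.8 to 88.0) and 72.3 (58.1 to 88.8). In myofibre-like cells Dmd had 1 UMI (4.33 CPM, 0.110 to 24.1) in TA labelled WT, 19 (115 CPM, 69.2 to 180) in TA labelled DMD, 0 in EOM labelled WT and 3 (7.21 CPM, 1.49 to 21.1) in EOM labelled DMD. Schwann-like cells had 385 CPM (276 to 522) in TA labelled WT and 121 (96.4 to 150) in TA labelled DMD. In EOM labelled WT and labelled DMD they had 227 (171 to 295) and 135 (104 to 174). Mural-like cells had 62.7, 36.5, 60.3 and 37.8 CPM in the same order of libraries, and endothelial-like cells 16.4, 18.8, 14.7 and 13.7. The direction thus differed between classes. The labels do not say which part of Dmd is altered in these rats, and 3' tags can lie outside it, so these levels do not check the labels.

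Cell composition differed between the libraries of both muscles. In TA, FAP/fibroblast-like cells, the fibro-adipogenic progenitors and matrix-producing cells of muscle, made up 16.7% (15.9 to 17.6) of the library labelled DMD and 0.096% (0.012 to 0.346), 2 cells, of the library labelled WT. Endothelial-like cells went the other way, at 35.4% (34.4 to 36.5) in TA labelled DMD and 75.6% (73.7 to 77.4) in TA labelled WT. Mural-like cells (21.5% against 8.64%), tenocyte-like cells (3.18% against 0.192%), macrophage/monocyte-like cells (4.17% against 0.864%) and satellite-like cells, the muscle stem cells (4.37% against 2.69%), had higher shares in TA labelled DMD. Shares are parts of a whole, so the lower endothelial-like share there by itself raises those of other classes. Satellite-like cells numbered 348 beside 2821 endothelial-like cells in TA labelled DMD, and 56 beside 1574 in TA labelled WT. By the cell counts, satellite-like and mural-like cells did not have a higher share of the cells that are not endothelial-like. Tenocyte-like and macrophage/monocyte-like cells still did. Myofibre-like cells had a lower one, at 1.29% (1.06 to 1.57) against 6.24% (5.24 to 7.37). With at least 1000 UMIs and at most 10% mitochondrial UMIs, the log2 share ratio of satellite-like cells in TA was 0.17 in place of 0.69 and that of macrophage/monocyte-like cells 0.69 in place of 2.23. At Leiden resolution 0.5 the log2 ratio of the FAP/fibroblast-like share in TA was 3.20 in place of 7.12, with 17 and 0 such cells, and that of tenocyte-like cells 1.31 in place of 3.88. With each library clustered alone, the ratio of myofibre-like cells was -0.89 in place of -2.27.

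In EOM, FAP/fibroblast-like cells made up 25.6% (23.8 to 27.4) of the library labelled DMD and 14.9% (13 to 17.0) of the library labelled WT, and endothelial-like cells 25.9% (24.1 to 27.7) and 43.8% (41.0 to 46.6). Macrophage/monocyte-like cells stood at 5.66% (4.75 to 6.70) and 2.64% (1.83 to 3.69), and myofibre-like cells at 6.81% (5.81 to 7.93) and 2.96% (2.09 to 4.06), in each case with the higher share in EOM labelled DMD. Satellite-like cells did not differ within counting error, at 9.95% (8.75 to 11.3) and 10.7% (9.07 to 12.6), nor did mural-like cells, at 6.86% (5.85 to 7.98) and 7.21% (5.83 to 8.78), although with at least 1000 UMIs and at most 10% mitochondrial UMIs the latter stood at 5.12% and 2.97%, a log2 ratio of 0.76 in place of -0.07. T cell-like cells were 1.90% against 0.801%, and 1.99% against 1.36% with each library clustered alone. Neutrophil-like cells were 1.59% of EOM labelled DMD and 0 of 1249 cells of EOM labelled WT, which allows a share of up to 0.240%.

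Between muscles, satellite-like cells had a higher share in EOM in both label pairs, 10.7% against 2.69% in the pair labelled WT and 9.95% against 4.37% in the pair labelled DMD. Erythroid-like cells were 2.74% of TA labelled WT, 3.11% of TA labelled DMD, 5.28% of EOM labelled WT and 0.442% of EOM labelled DMD. Unnamed clusters held 0.336%, 3.39%, 4.16% and 5.48% of the 4 libraries in that order, and 1 of them, led by MHC class II genes, held 244 cells of TA labelled DMD. Libraries differed in depth per cell and in the share of barcodes with under 200 genes (29.4%, 1.26%, 20.7% and 15%), both of which can move these shares. The share of a class also moves those of the others in its library, in EOM as in TA.

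**Figure D1:**
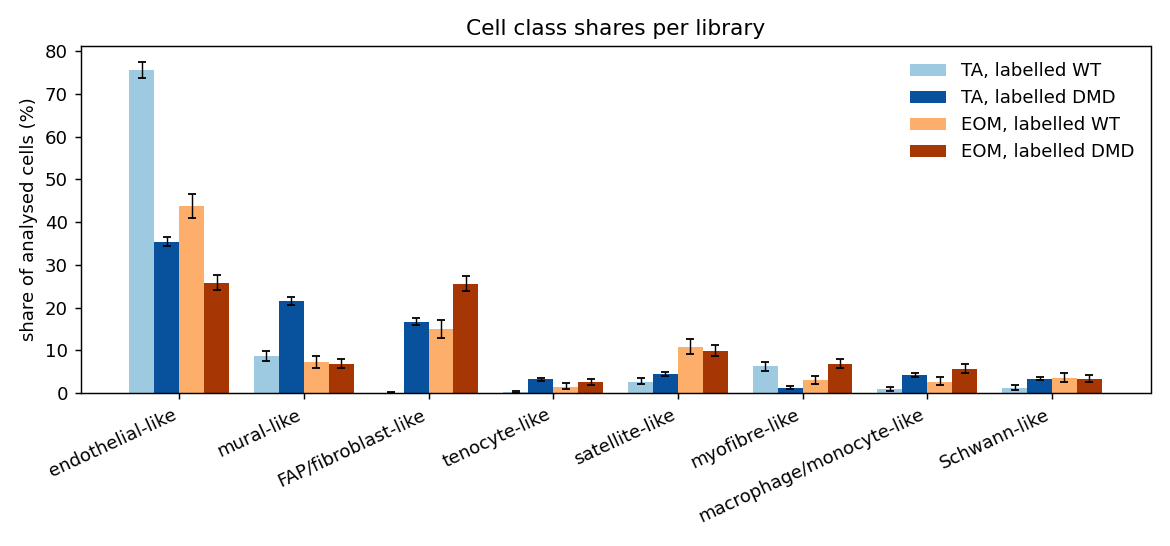
Share of analysed cells (%, vertical axis) in 8 cell classes (horizontal axis) for each of the 4 libraries. Bars are shares of 1 library each and error bars exact 95% binomial intervals for counting error, with FAP/fibroblast-like cells at 0.096% in TA labelled WT and 16.7% in TA labelled DMD.

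Satellite-like cells of TA differed strongly between labels in cell cycle inhibitors and muscle differentiation genes. The p21 gene Cdkn1a (ENSRNOG00000000521) stood at 412 CPM (370 to 456) in TA labelled DMD and 27.1 (12.4 to 51.4) in TA labelled WT, 15.2-fold higher (7.92 to 33.5). The Ink4a/Arf gene Cdkn2a (ENSRNOG00000059837), a marker of senescence, had 163 UMIs against 1, a ratio of 62.5 (11.1 to 2484). Myog, the transcription factor of terminal muscle differentiation, had 469 UMIs against 0, at least 59.9-fold higher, and Spp1, which encodes osteopontin, 323 against 0, at least 41.3-fold higher. The calcium-binding protein gene S100a6 was 147-fold higher (71.1 to 365), at 3087 against 21 CPM. Lower in TA labelled DMD were Nppc, which encodes C-type natriuretic peptide (25.4 against 5818 CPM, 229.5-fold lower, 151 to 367), and, with 3 UMIs each in TA labelled DMD, the bone morphogenetic protein antagonist Chrdl2 (92.1-fold lower, 30.7 to 454) and the neurotrophin receptor Ntrk2 (66.9-fold lower, 22.1 to 332).

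The fixed lists followed these genes. In TA satellite-like cells, senescence and cell cycle arrest had a median log2 ratio of 1.53 (0.69 to 1.86, 15 members, percentile 100), with Cdkn2b at 47 UMIs against 1 (ratio 18, 3.08 to 727) and Timp1 3.79-fold higher (2.70 to 5.47), while Gdf15 went the other way, 10.8-fold lower (4.87 to 26.9). Myogenic activation and differentiation had a median of 2.0 (1.57 to 2.43, 15 members, percentile 100). Among its members were the cardiac actin gene Actc1 (172 UMIs against 0, at least 22.0-fold higher), the fusion factor Mymk (37 against 0, at least 4.73-fold) and the cell cycle inhibitor Cdkn1c (7.81-fold higher, 4.28 to 15.9), whereas Myod1 was 1.58-fold lower (1.27 to 1.97) and Myf5 differed by less than counting error. Without the Myog-led cluster that median was 0.69. In thinned cells the log2 ratios of Cdkn1c and Cdkn2b were 0.55 and 0.89 in place of 2.64 and 2.30. TSH receptor and cAMP signalling had a median of -1.17 (-1.34 to -0.84, 12 members, percentile 0), with the thyrotropin receptor Tshr 6.33-fold lower (2.5 to 18.1), the phosphodiesterase Pde4b 2.92-fold lower (2.07 to 4.14), the G protein subunit Gnas 2.17-fold lower (2.03 to 2.33) and Nr4a1 4.14-fold lower (3.34 to 5.15). With all members that had a UMI, the medians of the arrest and TSH receptor lists were 0.55 and -0.52. Proliferation also stood higher in these cells, at 0.76 (0.17 to 1.26, 5 members, percentile 99.6). It was 0.11 for the 3 members that pass the free RNA guard and 0 in thinned cells.

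Satellite cell quiescence in TA had a median of -0.33 (-0.52 to -0.22, 16 members, percentile 2.09), which was -0.18 without the Myog-led cluster and -0.53 in thinned cells. The Notch target Heyl was 5.45-fold lower (3.77 to 8.0) and the calcitonin receptor Calcr 3.78-fold lower (2.61 to 5.52) in TA labelled DMD. The stem cell factor Pax7 stood at 281 CPM (247 to 319) against 352 (291 to 421), with overlapping intervals. Its log2 ratio turned to 0.15 in thinned cells. Interferon response had a median of -0.49 (-0.84 to -0.02, 11 members, percentile 1.86), with Isg15 3.91-fold lower (2.21 to 7.04), but turned to 0.14 in cells thinned to 1000 UMIs. Genes of other cell types moved as well. The capillary, arterial and venous endothelial lists had medians of 1.98 (9 members), 1.87 (3 members) and 2.12 (5 members), and fibrillar matrix genes 1.44 (18 members), which was 0.51 for the 8 members that pass the free RNA guard. The endothelial gene Fabp4 stood at 1971 CPM in satellite-like cells of TA labelled DMD and 66.1 in those of TA labelled WT.

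Different clusters held these cells. Of 348 satellite-like cells in TA labelled DMD, 245 fell in a cluster with Cdkn2a and Fgfr4 among its leading genes, 62 in the Nppc-led cluster and 41 in the Myog-led cluster, whereas 50 of 56 cells of TA labelled WT lay in the Nppc-led cluster. The first and the last of these held 6 and 0 cells of TA labelled WT, so each may be that 1 library. After thinning to 1000 UMIs, Cdkn2a was seen in 15.9% (11.0 to 21.9) of 189 satellite-like cells of TA labelled DMD and in 0 of 55 cells of TA labelled WT, which allows up to 5.45%. Endothelial-like cells of TA labelled DMD showed it in 0.051% of 1947 cells. Cdkn1a was seen in 29.1% (22.7 to 36.1) against 3.64% (0.444 to 12.5), beside 18% and 17.5% in endothelial-like cells. Myog was seen in 12.7% (8.31 to 18.3) against 0, and in 0 endothelial-like cells of either library. Thinning left out 159 of 348 satellite-like cells of TA labelled DMD and 1 of 56 of TA labelled WT, whose medians were 1080 and 6142 UMIs, against 1830 and 2290 in endothelial-like cells. Unthinned shares were 22.7% and 1.79% for Cdkn2a, 39.1% and 12.5% for Cdkn1a and 7.47% and 0% for Myog.

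**Figure D2:**
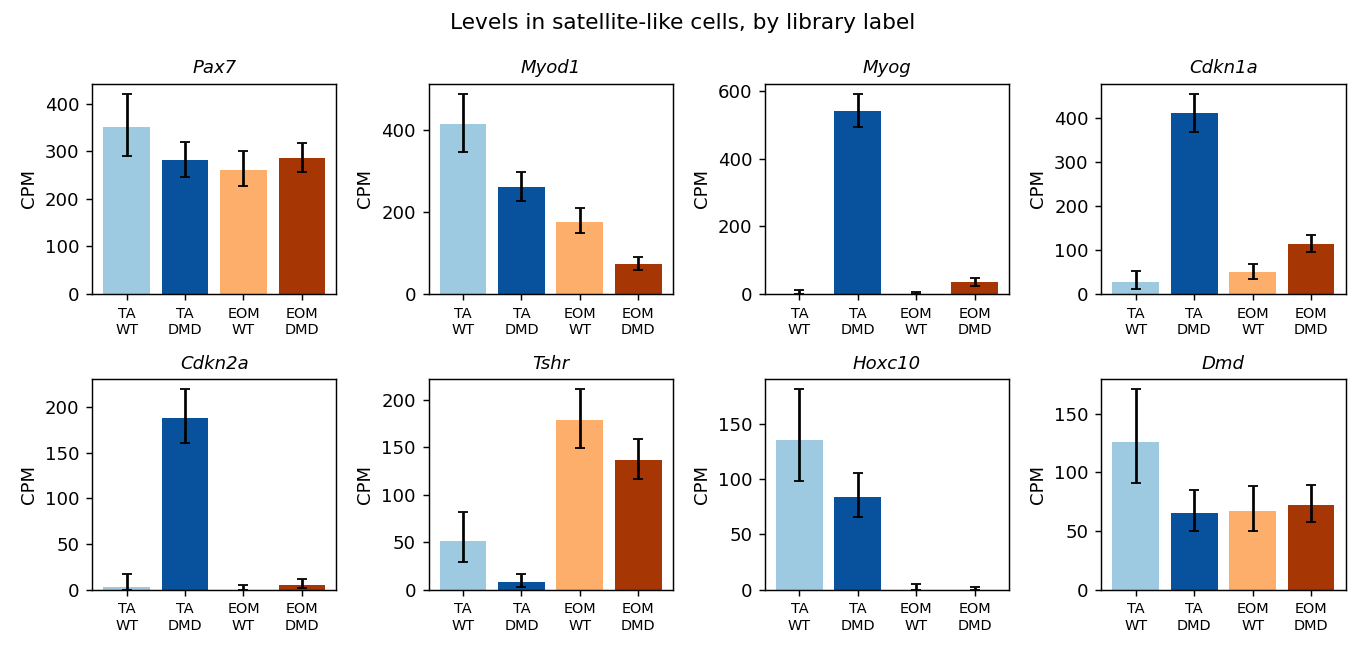
Levels of 8 genes (CPM, vertical axis) in satellite-like cells of the 4 libraries (horizontal axis). Bars are sums over the cells of 1 library each and error bars exact 95% Poisson intervals for counting error, with Cdkn2a at 188 CPM in TA labelled DMD and Tshr at 179 and 136 CPM in the EOM libraries labelled WT and DMD.

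In EOM satellite-like cells, Cdkn1a was 2.29-fold higher (1.59 to 3.36) in EOM labelled DMD, at 114 against 49.9 CPM, and Cdkn1c 2.42-fold higher (2.01 to 2.93). Cdkn2a had 7 UMIs against 0, and the intervals overlapped, at 2.26 to 11.6 and 0 to 4.84 CPM. Myog had 43 against 0, at least 8.77-fold higher, with all 43 in 2 of 225 cells. Ranked highest were Spp1 (4.99-fold, 3.12 to 8.38), the chemokine gene Cxcl1 (3.08-fold, 2.62 to 3.65) and the methyl-CpG-binding protein gene Mbd2 (3.15-fold, 2.15 to 4.76). Ranked lowest were the heat shock genes Hspa1b (7.14-fold lower, 6.38 to 8.01) and Hsph1 (3.57-fold lower, 2.85 to 4.51) and Pmepa1 (4.09-fold lower, 2.86 to 5.94). Spry1, a growth factor signalling inhibitor linked to quiescence, was 2.01-fold higher (1.76 to 2.30), Nr4a1 2.97-fold higher (2.41 to 3.69), Gnas 2.45-fold lower (2.32 to 2.59) and Myod1 2.40-fold lower (1.83 to 3.16). Pax7 did not differ beyond counting error.

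Among the lists in EOM satellite-like cells, senescence and cell cycle arrest had a median of 0.36 (0.09 to 0.65, 9 members, percentile 99.8), which was 0.01 with at least 1000 UMIs and at most 10% mitochondrial UMIs. Interferon response stood at 0.39 (0.16 to 0.66, 11 members) and inflammatory cytokines and chemokines at 0.83 (0.71 to 1.06, 6 members), and the latter was 0.07 for the 3 members that pass the free RNA guard. The myogenic list was at 0.28 (-0.05 to 0.39), quiescence at -0.01 (-0.17 to 0.11) and the TSH receptor list at -0.20 (-0.43 to -0.09, percentile 22.4), none of them apart from random lists by both criteria. Basement membrane genes stood at -0.39 (-0.58 to -0.24, 10 members), with Col15a1 2.12-fold lower (1.83 to 2.44). The venous endothelial list, genes of another cell type, stood at 0.76 (3 members). Nearly all of these cells, 132 of 134 and 225 of 225, lay in the Nppc-led cluster. After thinning, Cdkn1a was seen in 9.87% (6.29 to 14.6) of 223 cells of EOM labelled DMD and 3.08% (0.845 to 7.69) of 130 cells of EOM labelled WT beside 33.0% and 21.7% of endothelial-like cells. Cdkn2a was seen in 0 cells of either library, which allows up to 1.35% and 2.31%, and Myog in 1 cell of EOM labelled DMD. Too shallow for thinning were 2 and 4 cells, and the medians were 5137 and 5801 UMIs against 2565 and 2211 in endothelial-like cells. Unthinned, Cdkn1a was seen in 36.4% and 17.2%, Cdkn2a in 1.33% and 0% and Myog in 0.889% and 0%.

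In TA endothelial-like cells, adhesion molecules and chemokines of activated and venous endothelium stood higher in the library labelled DMD. The selectin genes Selp (163 against 7.67 CPM, 21.2-fold, 14.8 to 31.6) and Sele (815 UMIs against 1, ratio 396, 70.9 to 15670) and the leukocyte adhesion genes Vcam1 (16.2-fold, 11.9 to 22.6) and Icam1 (20.7-fold, 13.8 to 32.4) were all higher. Ranked highest were the monocyte chemokine gene Ccl7 (3403 UMIs against 2, ratio 827, 229 to 6832), Fgl2 (52.2-fold, 41.8 to 66.1) and the galectin gene Lgals3 (27.8-fold, 22.6 to 34.7). Ccl7 was also among the leading genes of a mural-like cluster with 145 cells of TA labelled DMD. Free RNA from such cells was not tested for it. Ranked lowest were Esm1 (21.2-fold lower, 18.3 to 24.7), the carbonic anhydrase gene Car2 (9.02-fold, 8.26 to 9.86) and Calhm5 (6.01-fold, 5.52 to 6.55). The venous and activated list had a median of 2.43 (2.29 to 2.57, 10 members, percentile 100). Capillary and metabolic endothelium stood at -1.0 (-1.03 to -0.96, 10 members, percentile 0) and arterial endothelium at -0.99 (-1.06 to -0.84, 7 members, percentile 0.02), with Rgcc 4.02-fold lower (3.90 to 4.14), the transcription factor Tcf15 2.68-fold lower (2.58 to 2.78) and the Notch ligand Dll4 2.29-fold lower (2.15 to 2.45).

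Inflammatory cytokines and chemokines in TA endothelial-like cells had a median of 1.61 (1.46 to 1.77, 10 members), interferon response -0.55 (-0.67 to -0.44, 17 members), with Isg15 2.14-fold lower (1.97 to 2.32), Notch ligands and targets -0.48 (-0.52 to -0.43, 8 members), and basement membrane -0.54 (-0.65 to -0.47, 11 members). Fibrillar matrix (1.84, 10 members) and complement (1.44, 6 members) also stood higher, but 2 and 1 of their members pass the free RNA guard, and senescence and cell cycle arrest turned from 1.02 to -0.02 for members that pass it. Most cells of TA labelled WT, 1069 of 1574, lay in a cluster with Car2, Calhm5 and Esm1 among its leading genes, whereas TA labelled DMD held 923 cells in a shallow cluster with Aif1l and Rbp7 among its leading genes, 703 in an interferon-led cluster and 677 in a cluster led by Selp and Sele that had 5 cells of TA labelled WT. With all measured members the arterial median was -0.24.

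In EOM endothelial-like cells, Vcam1 was 7.64-fold higher (4.80 to 12.8) in the library labelled DMD, the serine protease gene Prss23 7.18-fold (4.77 to 11.2) and Lgals3 4.90-fold (3.70 to 6.60). The flow-responsive transcription factor Klf2 was 6.91-fold lower (6.0 to 7.99), Hrct1 5.79-fold lower (4.71 to 7.19) and Depp1 4.25-fold lower (3.67 to 4.95). Unlike in TA, the capillary list stood at 0.02 (-0.09 to 0.10), the arterial at 0.06 (-0.24 to 0.24) and the venous at 0.11 (0.03 to 0.33, percentile 91.3), though the difference between muscles was not tested. Within the capillary list Gpihbp1, which anchors lipoprotein lipase, was 2.83-fold higher (2.61 to 3.06) and Rgcc 1.87-fold lower (1.78 to 1.95). Immediate early and heat shock genes had a median of 0.43 (0.36 to 0.46, 14 members, percentile 100), with Fos 2.01-fold higher (1.93 to 2.10) and Hspa1b 3.65-fold lower (3.37 to 3.96). Basement membrane genes stood at -0.44 (-0.58 to -0.35, 10 members). Inflammatory cytokines and chemokines stood at 1.72 (1.30 to 1.97, 7 members) and at -0.20 for the 3 members that pass the free RNA guard. In EOM labelled WT 305 of 547 cells lay in the Car2-containing cluster, and in EOM labelled DMD 309 of 585 in the interferon-led cluster. The interferon response list stood at 0.16 (-0.002 to 0.21, 17 members) and was not apart from random lists by both criteria.

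**Figure D3:**
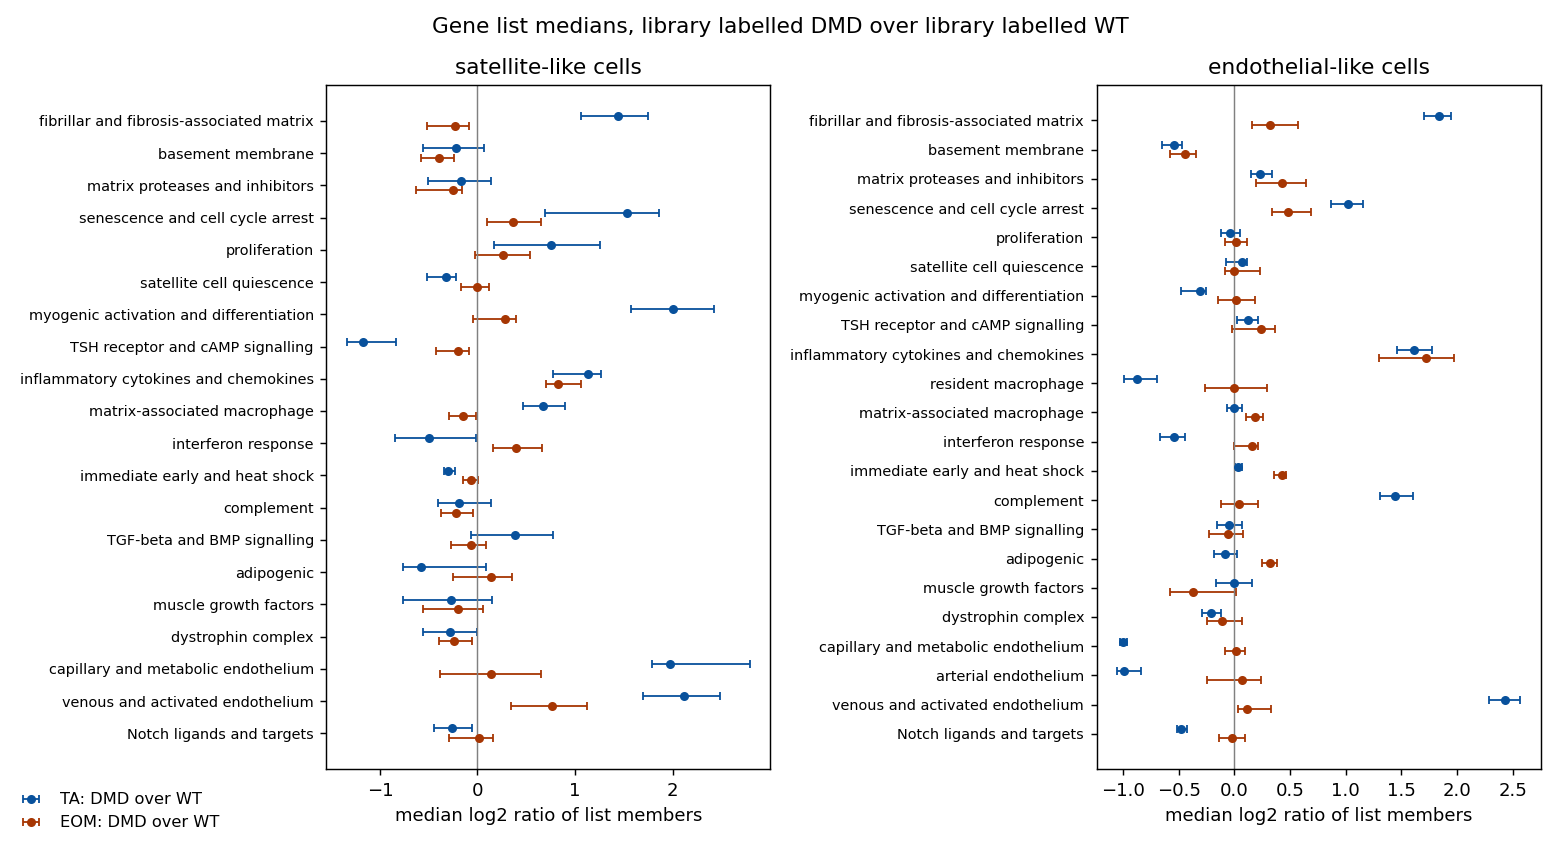
Median log2 ratio (horizontal axis) of the members of each gene list (vertical axis) in satellite-like and endothelial-like cells, library labelled DMD over library labelled WT, in TA and EOM. Bars are 95% counting intervals from redrawn counts, with the venous and activated list in endothelial-like cells at 2.43 in TA and 0.11 in EOM.

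FAP/fibroblast-like cells could be compared between labels in EOM alone, because TA labelled WT held 2 of them. Matrix genes stood lower in EOM labelled DMD. The collagen genes Col1a1 (1893 against 6187 CPM, 3.27-fold lower, 3.17 to 3.37) and Col3a1 (2.38-fold lower, 2.32 to 2.44) and the stromelysin gene Mmp3 (3.71-fold lower, 3.19 to 4.32) ranked lowest. The fibrillar and fibrosis-associated matrix list had a median of -0.41 (-0.49 to -0.29, 24 members, percentile 0), with Col5a1 2.12-fold lower (1.80 to 2.49) and the matricellular gene Postn 1.51-fold lower (1.28 to 1.78). Ranked highest were Ier5l (3.02-fold, 2.27 to 4.08), Ifi27l2b (2.30-fold, 2.16 to 2.46) and Fgl2 (2.28-fold, 2.0 to 2.61). Inflammatory cytokines and chemokines stood at 0.56 (0.44 to 0.73, 10 members, percentile 100), with the interleukin gene Il6 3.41-fold higher (2.24 to 5.42) and the chemokine gene Ccl2 2.91-fold higher (2.45 to 3.47). Complement genes were at 0.16 (0.09 to 0.30, 12 members) and TGF-beta and BMP signalling at 0.06 (-0.14 to 0.12). Of these cells 185 of 186 and 573 of 578 lay in 1 cluster.

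Between muscles, satellite-like cells carried positional genes of their origin in both label pairs. In the pair labelled WT, the limb gene Hoxc10 (ENSRNOG00000016149) had 0 UMIs in EOM and 45 in TA, at least 34.3-fold lower, and Hoxc9 0 against 25, at least 19.1-fold lower. Foxc1, a transcription factor of head and eye development, had 28 UMIs against 0, at least 4.08-fold higher. Ranked highest were the semaphorin gene Sema3d (80 UMIs against 3, ratio 11.6, 3.85 to 57.7), Medag (6.25-fold, 3.30 to 13.3) and the imprinted gene Nnat (6.26-fold, 3.20 to 14.0). Besides Hoxc10, Prr32 (3 UMIs against 60, 45.8-fold lower, 14.9 to 228) and the calcium channel subunit gene Cacng1 (11.8-fold lower, 7.65 to 18.9) ranked lowest. Tshr (ENSRNOG00000003972) was 3.49-fold higher (2.10 to 6.17) in EOM, at 179 against 51.1 CPM. The limb and trunk list had a median of -2.36 (-2.72 to -2.01, 6 members, percentile 0), although its member Pitx1 had 14 UMIs in EOM and 0 in TA. Interferon response stood at -0.72 (-0.99 to -0.33, 10 members), with Isg15 15.1-fold lower (5.86 to 49.6). Genes of other cell types also stood lower in EOM, with resident macrophage genes at -1.79 (-2.01 to -1.50, 3 members) and capillary endothelial genes at -0.97 (-1.44 to -0.45, 3 members). TA labelled WT gave 56 of these cells.

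In the pair labelled DMD the positional genes kept these directions. Hoxc10 had 0 UMIs in EOM and 73 in TA, at least 34.9-fold lower, and the limb muscle precursor gene Lbx1 0 against 26, at least 12.4-fold lower. Foxc1 was 15-fold higher (6.25 to 47.3). The limb and trunk list stood at -2.0 (-2.30 to -1.82, 7 members), and Pitx1 again went against its list, with 21 UMIs in EOM and 0 in TA. Ranked highest were Nppc (147-fold, 97.3 to 235), Chrdl2 (413 UMIs against 3, ratio 95.9, 32.6 to 467) and Ntrk2 (204 against 3, ratio 47.4, 16.0 to 232). Ranked lowest were the troponin gene Tnnt2 (2 UMIs against 161, 116-fold lower, 31.5 to 962), the stress-response gene Ankrd1 (24.8-fold lower, 16.1 to 40.0) and Ecm1 (1 against 143, 205-fold lower, 36.3 to 8164). Tshr was 16.9-fold higher (8.04 to 42.7) in EOM, Cdkn2a 33.4-fold lower (15.9 to 84.5), Cdkn1a 3.61-fold lower (2.96 to 4.41) and Myog 15.7-fold lower (11.4 to 21.9), where its EOM UMIs came from 2 of 225 cells. Senescence and cell cycle arrest had a median of -1.0 (-1.20 to -0.69, 13 members), the myogenic list -1.70 (-1.97 to -1.49, 15 members), TSH receptor and cAMP signalling 0.68 (0.39 to 0.91, 12 members) and quiescence 0.43 (0.28 to 0.62, 16 members). After thinning, Tshr was seen in 13.9% (9.65 to 19.2) of cells of EOM labelled DMD, 20.8% (14.2 to 28.8) of EOM labelled WT, 0 of 189 cells of TA labelled DMD and 3.64% (0.444 to 12.5) of TA labelled WT, beside 0.194%, 0%, 0.051% and 0% of endothelial-like cells. Unthinned, the satellite-like shares were 49.3%, 58.2%, 2.01% and 21.4%. The cells lay in the Nppc-led cluster in EOM and mostly outside it in TA, and capillary endothelial genes stood lower in EOM (-2.65, 9 members).

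In endothelial-like cells of the pair labelled WT, the taurine transporter gene Slc6a6 (4.76-fold, 3.75 to 6.06) and Apold1 (3.46-fold, 3.11 to 3.85) ranked among the highest in EOM over TA, and Rbp7 (3.47-fold lower, 2.99 to 4.03), Gmfg (3.15-fold lower, 2.46 to 4.07) and the chemokine receptor gene Cxcr4 (2.67-fold lower, 2.31 to 3.10) ranked lowest. Interferon response stood at 0.35 (0.14 to 0.44, 17 members) and TGF-beta and BMP signalling at 0.33 (0.20 to 0.48, 10 members). Limb and trunk genes stood at -1.39 (-1.74 to -1.06, 3 members). In the pair labelled DMD, the phospholipid transporter gene Abcb4 (25.1-fold, 17.7 to 36.5) and Esm1 (5.02-fold, 4.10 to 6.14) ranked among the highest, and Ccl7 (13.1-fold lower, 10.0 to 17.5), Angptl4 (8.80-fold lower, 6.01 to 13.4) and Sele (7.73-fold lower, 5.07 to 12.4) ranked lowest. There the venous list stood at -0.71 (-0.92 to -0.61, 10 members), the capillary at 0.81 (0.74 to 0.88, 10 members), the arterial at 0.67 (0.58 to 0.75, 7 members), interferon response at 0.68 (0.65 to 0.87, 17 members) and Notch ligands and targets at 0.48 (0.39 to 0.57, 8 members). These cells lay largely in the Car2-containing cluster in both libraries labelled WT, and in the pair labelled DMD in the interferon-led cluster in EOM and in 3 clusters in TA.

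FAP/fibroblast-like cells of the pair labelled DMD differed widely between muscles. The carboxylesterase gene Ces1d (709-fold, 326 to 1933) and the progenitor marker Pi16 (17.4-fold, 15 to 20.1) ranked among the highest in EOM. The lubricin gene Prg4 (16.0-fold lower, 13.7 to 18.7), the WNT antagonist gene Sfrp1 (12.8-fold lower, 11.5 to 14.1) and the bone morphogenetic protein gene Bmp5 (93.6-fold lower, 47.2 to 218) ranked lowest. Fibrillar and fibrosis-associated matrix had a median of -0.56 (-0.59 to -0.51, 24 members, percentile 0), with Comp 7.07-fold lower (6.11 to 8.22) and Col3a1 1.5-fold lower (1.47 to 1.54), and WNT signalling -0.43 (-0.66 to -0.29, 8 members), which was 0.02 with all members that had a UMI. Muscle growth factors stood at 0.73 (0.56 to 0.89, 9 members, percentile 100), with the growth factor genes Igf1 3.11-fold higher (2.99 to 3.23) and Hgf 2.0-fold higher (1.47 to 2.65). Immediate early and heat shock genes stood at 1.02 (0.99 to 1.04, 14 members) and inflammatory cytokines and chemokines at 1.04 (0.89 to 1.11, 10 members), with Cxcl1 5.34-fold higher (4.90 to 5.84). The cells came from 1 cluster in EOM and from 2 others in TA (1104 and 208 of 1331 cells), with medians of 7533 and 952 UMIs, and capillary endothelial genes stood at -2.50 (9 members). Taking the mean over cells of each cell's CPM, the matrix median was -0.26.

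Macrophage/monocyte-like cells reached 50 cells in both libraries in the pair labelled DMD alone. Genes of resident macrophages stood higher in EOM, with a list median of 1.65 (1.37 to 1.83, 10 members, percentile 100). The transglutaminase gene F13a1 was 10.1-fold higher (7.91 to 13.1), the hyaluronan receptor gene Lyve1 9.35-fold (7.01 to 12.7) and the haemoglobin scavenger receptor gene Cd163 8.13-fold (6.09 to 11.1). The lectin genes Cd209f (192 UMIs against 0, at least 42.7-fold) and Fcna (15.8-fold, 12.5 to 20.2) and the complement gene C6 (27.6-fold, 13.2 to 69.2) ranked highest. Matrix-associated macrophage genes stood lower, at -0.96 (-1.17 to -0.80, 15 members, percentile 0) and at -0.60 for members that pass the free RNA guard, with the fatty acid-binding protein gene Fabp5 9.09-fold lower (7.20 to 11.6), Gpnmb 5.02-fold lower (4.06 to 6.25) and Spp1 at 0 UMIs against 97, at least 48.4-fold lower. In TA labelled DMD, however, 11 endothelial genes reached a median of 22.1% of their endothelial level in this class (quartiles 18.9 and 34.6). This is close to the 25% of the guard, which 6 of 10 measured venous endothelial genes pass. The guard therefore cannot separate free RNA from expression in this contrast. Inflammatory cytokines and chemokines stood at 1.27 (1.09 to 1.43, 16 members), with Il1b 5.41-fold higher (4.75 to 6.18), while MHC class II genes stood at -0.02 (-0.08 to 0.01, 6 members). The unnamed cluster led by MHC class II genes, with 244 cells of TA and 13 of EOM labelled DMD, was not part of this class. Clu, Cavin1 and Tm4sf1 (105-fold, 68.7-fold and 87.2-fold lower) ranked lowest and are genes that vessel and stromal cells express, and the capillary endothelial list stood at -3.14 (9 members). In EOM 64 and 64 cells, and in TA 144 and 188, lay in the 2 macrophage clusters, with medians of 9408 and 1240 UMIs.

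Scaling with TMM moved all ratios of a class and contrast together. The log2 shift was 0.08 and 0.16 for satellite-like cells in the TA and EOM disease contrasts and 0.11 and 0.18 in the tissue contrasts labelled WT and DMD. For endothelial-like cells it was 0.12 and 0.10 in the disease contrasts and -0.0002 and -0.0238 in the tissue contrasts labelled WT and DMD, for FAP/fibroblast-like cells 0.14 in EOM and 0.13 between tissues labelled DMD, and for macrophage/monocyte-like cells 0.11. Values above are without that shift. Counting a member with 0 UMIs at the limit of 3 counts moved list medians of satellite-like cells in TA from 2.0 to 1.84 for the myogenic list, from 1.44 to 0.89 for fibrillar matrix and from 2.12 to 1.19 and 1.87 to 0.94 for the venous and arterial lists. It moved the limb and trunk list to -1.88 and -1.84 in the tissue contrasts labelled WT and DMD.

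Across genes measured in both muscles, the disease ratios of TA and EOM had a Spearman correlation of 0.362 in satellite-like cells (1761 genes), 0.597 in endothelial-like cells (1875 genes) and 0.597 in mural-like cells (1826 genes). The Pearson correlations were 0.438, 0.667 and 0.700. They describe these libraries and were not tested.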

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

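Chosen after the results were seen were the tests on lysed fibroblasts, on cluster naming, on disease state or digestion, on free RNA, on shallow cells, on the small cluster, on exchanged labels and on the likeness of endothelial gene shares between classes. An earlier small cluster test on 20 members picked for being higher was dropped, since that choice decides its outcome, as was a free RNA test that set them against classes that express them. The bound that a counting interval had to exceed in the tests on shallow cells and on the small cluster, a log2 ratio of 0.5, was also set after the values were seen, and 3 of these 4 intervals do not exceed the bound of 1 written earlier. The share of myofibre-like cells went opposite ways in the 2 muscles, with a log2 ratio of DMD over WT of -2.27 in TA and 1.19 in EOM. In TA it was -0.89 with each library clustered alone, and the difference between muscles was not tested. Interferon response in satellite-like cells also did, with medians of -0.49 in TA and 0.39 in EOM, but the TA median was 0.14 in thinned cells, and that difference was not tested either.

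TA labelled WT held 2 FAP/fibroblast-like cells. Lysed fibroblasts would leave their transcripts behind, and 6 of their markers stood in endothelial-like cells at a median of 0.129 of the level in EOM labelled WT, with Gsn apart at 0.703. These 6 were the markers with at least 5 CPM in endothelial-like cells of EOM labelled WT. That choice favours a low ratio, so the test does not decide on lysis. Loss in the cell filters is argued against by the left-out barcodes, whose marker share was 3.77% of that of the kept cells of EOM labelled WT, and naming by cells with 5 or more Dcn UMIs, 0.720% against 17.9%, 20.2% and 33.3% in TA labelled DMD, EOM labelled WT and EOM labelled DMD. Disease state or digestion of this library cannot be told apart, because there was 1 library per group. Either could account for it, lysis stays open, and fewer such cells in the muscle stays untested.

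Arrest and differentiation genes stood higher in TA satellite-like cells labelled DMD. Over all 15 measured members of each list, thinning, which turned interferon response, left a median log2 ratio of 2.39 (1.79 to 2.88, myogenic) and 1.57 (0.59 to 2.06, arrest). The members were chosen by their level with cells under 1000 UMIs included, which favours a median above 0. The test therefore does not decide on those cells, which thinning leaves out, as the whole cause. Thinning left out 159 of 348 satellite-like cells, and Myog was seen in 12.7% after it and 7.47% before. The Myog-led cluster may thus weigh more in the thinned medians, and thinning without it was not run. Thinning keeps the expected proportions of each cell, so it cannot decide on other effects of low depth. Without the Myog-led cluster the medians were 1.17 (0.54 to 1.73, arrest) and 0.69 (0.54 to 1.16, myogenic), while the myogenic median was 2.0 with it. Both intervals lie above 0, but the members were chosen by their level with that cluster included. This choice favours a median above 0, and 4 of the 15 myogenic members had 0 UMIs in 1 library. The test therefore does not decide on a small cluster of differentiating cells as the whole cause. Neither interval exceeds the bound of 1 written earlier, so a large part played by that cluster stays open. Free RNA is argued against for Myog and Cdkn2a, seen in 12.7% and 15.9% of thinned satellite-like cells and in 0 and 0.051% of endothelial-like cells, but cannot be told for the other 18 members at least 2-fold higher, of which 11 had their highest other level in myofibre-like cells. Myog is also a fixed marker that names satellite-like clusters, so the naming favours its presence there. Cdkn2a is not such a marker. Exchanged labels cannot be told apart from the stated ones. Dmd had a log2 ratio of -0.85 in these cells and was also lower in Schwann-like and mural-like cells labelled DMD of both muscles. In TA myofibre-like cells labelled DMD it was higher. Its 3' tags can lie outside the altered part, so Dmd does not decide the question, and disease state stays open and untested.

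Endothelial genes stood in other classes of TA labelled DMD, where 11 of them reached 9.55% of their endothelial level in satellite-like, 11.7% in FAP/fibroblast-like, 22.1% in macrophage/monocyte-like and 20.9% in mural-like cells. In the other libraries satellite-like cells had 0.384% (TA labelled WT), 0.230% (EOM labelled WT) and 0.181% (EOM labelled DMD). Free RNA could account for the FAP/fibroblast-like and satellite-like shares, which were alike at a ratio of 1.22, but cannot be told for macrophage/monocyte-like and mural-like cells, whose higher share was 2.31 times the satellite-like one, within the spread between genes. Doublets with endothelial cells could contribute, since the 10% of satellite-like cells with most of these UMIs held 51.7% of them, but a spread by depth alone would give 45.0% (at most 47.4% in 200 draws), so this test separated them poorly. No biological explanation was tested.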

How the results depend on the processing

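Chosen after the data were seen were the members that pass the free RNA guard and the satellite-like cells without the Myog-led cluster. Of 2869 values from alternatives, 2121 stayed within counting error, 717 moved beyond it without a called value changing sign, and 31 changed sign or went to 0. Of the 194 for results treated in full, 144 stayed and 50 moved. All values below are log2, with DMD over WT named by the muscle and EOM over TA by the label, and the cause was not tested. No paired analysis was possible because the labels pair no samples and each group has 1 library.

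For shares in TA, FAP/fibroblast-like cells stood at 9.41 with each library alone and 3.20 at resolution 0.5 (7.12 as reported). Endothelial-like cells in TA stood at -1.02 without immune-like cells, -1.26 with doublet calls kept, -1.04 with each library alone and at resolution 0.5, and -1.20 at resolution 2.0. With at least 1000 UMIs and at most 10% mitochondrial UMIs, shares stood at -0.94 (endothelial-like, EOM), 0.69 (macrophage/monocyte-like, TA), 0.17 (satellite-like, TA) and, turned, -1.43 (neutrophil-like, TA, 1.94 as reported). At resolution 0.5 macrophage/monocyte-like cells stood at 2.93 (TA) and, turned, -0.12 (DMD), and with each library alone at -0.24 (DMD).

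In endothelial-like cells of TA, the arterial list stood at -0.82 (1000 UMIs and 10%), -0.72 (thinned), -0.755 (doublet calls kept), -0.24 (all members) and -0.75 (mean over cells). The capillary list stood at -0.88 (TMM), -0.78 (1000 UMIs and 10%), -0.86 (thinned), -0.83 (doublet calls kept) and -0.86 (mean over cells), and the venous list at 2.18 (1000 UMIs and 10%), 2.10 (doublet calls kept), 2.285 (mean over cells) and 2.90 (prior of 1 CPM). In EOM the arterial list stood at -0.28 (1000 UMIs and 10%) and the capillary at 0.11 (TMM).

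In satellite-like cells of TA, arrest stood at 0.55 (all members) and 1.91 (prior of 1 CPM), the myogenic list at 0.69 (without the Myog-led cluster) and 2.59 (prior of 1 CPM), quiescence at -0.18 (without the Myog-led cluster) and -0.53 (thinned), and the TSH receptor list at -0.52 (all members). In EOM, arrest stood at 0.75 (guard) and 0.00795 (1000 UMIs and 10%), the myogenic list at 0.41, the TSH receptor list at -0.0586 and quiescence at 0.13 (TMM) and -0.21 (thinned). In FAP/fibroblast-like cells, matrix stood at -0.43 (TMM), -0.62 (1000 UMIs and 10%), -0.41 (thinned), -0.51 (doublet calls kept) and -0.26 (mean over cells) for DMD, and at -0.29 (TMM) in EOM. In macrophage/monocyte-like cells (DMD), matrix-associated genes stood at -0.60 (guard) and -0.75 (mean over cells) and resident genes at 1.23 (1000 UMIs and 10%) and 1.90 (mean over cells).

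Thinning turned, in satellite-like cells, Pax7 to 0.15 (TA) and 0.0783 (WT), immediate early genes to 0.0804 (TA), interferon response to 0.14 (TA), and proliferation to 0 (TA) and -0.0157 (WT), and in FAP/fibroblast-like cells resident macrophage genes to 0.0322 (DMD). The mean over cells turned immediate early genes of satellite-like cells to 0.0143 (TA). The guard turned arrest to -0.0166 (TA), -0.0520 (EOM) and 0.0943 (DMD) in endothelial-like, -0.0885 (EOM) in FAP/fibroblast-like and -0.25 (WT) in satellite-like cells; inflammatory genes to -0.20 (EOM, endothelial-like) and -0.36 (TA, satellite-like); matrix to 0.0590 (DMD, endothelial-like) and -0.28 (WT, satellite-like). It also turned matrix proteases to -0.0630 (TA, endothelial-like), interferon response to -0.10 (EOM, FAP/fibroblast-like), and TGF-beta signalling to 0.0557 and quiescence to 0.34 (DMD, macrophage/monocyte-like). All members turned WNT signalling to 0.0155 and myogenic genes to 0.0238 (DMD) and arrest to -0.0348 (EOM) in FAP/fibroblast-like cells, and inflammatory genes to 0.16 (DMD, endothelial-like) and 0.18 (WT, satellite-like). With 1000 UMIs and 10%, inflammatory genes turned to -0.0183 (WT) and myogenic genes at 0.15 (DMD) in endothelial-like cells. Depth limits TA labelled DMD most, where 42.8% of kept cells had under 1000 UMIs.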

Other observations

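The Y-linked genes Eif2s3y and Kdm5d were seen in each library. Of the other Y-linked genes measured, Usp9y had 3 UMIs in endothelial-like cells of TA labelled WT, 5 in TA labelled DMD, 2 in EOM labelled WT and 3 in EOM labelled DMD. Ddx3y had 1, 0, 0 and 0 there. In endothelial-like cells Eif2s3y stood at 61.9 CPM (54.3 to 70.2) in TA labelled WT, 71.3 (65.6 to 77.4) in TA labelled DMD, 74.4 (60.9 to 90.0) in EOM labelled WT and 61.4 (50.1 to 74.4) in EOM labelled DMD, and Kdm5d at 33.0, 26.0, 33.7 and 25 CPM. Mast cell-like cells were found in EOM labelled DMD, 14 cells or 0.619% (0.339 to 1.04), and in 0 cells of the other 3 libraries. Schwann-like cells made up 1.25%, 3.34%, 3.52% and 3.32% of the 4 libraries in the same order.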
